A study of Homo sapiens with 9 samples.

How the data were processed

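RNA was taken from PANC-1 cells 72 h after transfection with 20 nM of a miR-520f mimic, 20 nM of a negative control mimic, or the lipid reagent alone, in 3 biological replicates of each, per the labels. Total RNA was isolated with TRIzol and converted to biotin-labelled cDNA with an Affymetrix GeneChip kit, per the labels' protocols. The authors deposited 1 table of log2 values for 22011 probe sets on 9 arrays. Partek 6.6, RMA and the human build hg18 were named in the submitters' processing notes, without their settings. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a probe set, so the deposited log2 values were normalized between arrays before this work. Any filter that the authors applied to probe sets was not given in the sources used here. The values ran from 2.23 to 13.6, with array medians of 4.22 to 4.34. RMA assumes that most genes do not change and compresses differences of dim probe sets, so fold changes near the lower end of the scale understate the true ones. No scanner images or background values were used, and no gene was therefore called absent.

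Probe sets were named through the annotation of the array platform. A single gene symbol was given for 14432 probe sets, several for 2408, and 5171 were not named here. Entrez identifiers matched 14404 of the single-gene probe sets to a gene table of assembly GRCh38.p14, and 0 symbols changed. For the 197 genes with more than 1 probe set the one with the highest mean over all arrays was used, which gave 14232 genes, 13734 of them protein-coding. Of those 197 genes, 12 had more than 1 probe set that changed against both controls, and 0 of them had opposite signs. No coordinates are given, since the build of the processing notes and that of the gene table differ. Samples were grouped by the label that names the treatment.

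Main tests were limma fits (limma 3.58.1, R 4.3.3) with 1 mean per group over all 9 arrays, 6 residual degrees of freedom and empirical Bayes moderation, with contrasts of miR-520f against non-transfected cells, miR-520f against the negative control, and the negative control against non-transfected cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Genes changed against both controls passed in both comparisons with the same sign. Genes higher, or lower, than both controls are the targets of the series' design text. The study itself used pairwise contrasts in Partek, per the series' design text, and an unmoderated fit of that kind was run as an alternative. The labels call the replicates biological without saying how cultures were separated, so p-values measure the spread between these arrays. On simulated values with the spread of the real genes, 14232 genes and a known set of them changed in the miR-520f group, the miR-520f comparisons against both controls recovered 55.2% of changes of 0.5, 97.0% of changes of 1 and 100% of changes of 2 on the log2 scale, and called 1 unchanged gene. Only 67, 67 and 66 genes were changed by these sizes, with independent noise. The real comparisons called 27.6% and 28.1% of the genes. The adjusted threshold depends on that share, so neither the recovery nor the number of false calls carries over to the real lists.

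The 31 gene lists were fixed before the data were examined. They covered epithelial and mesenchymal markers, TGF-beta pathway components and target genes, ADAM and matrix proteases, and matrix and integrins. Further lists held S phase, G2 and M phase, cell cycle inhibitors and G1 regulators, interferon response, NF-kappaB and inflammation, and p53 targets. Others held the integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, hypoxia and glycolysis, MAPK output, YAP targets, apoptosis and microRNA machinery. The rest were published targets of microRNAs of related seed, targets the study is known for, drug resistance and stemness, and ribosomal proteins. Also among them were immediate early and heat shock genes, replication-dependent histones, and fibroblast, endothelial, immune, acinar and endocrine markers. Lists with at least 5 measured members (29) were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. In a simulation in which the G2 and M phase list was raised by 0.3 on the log2 scale, camera called that list and 0 others. The simulated genes varied independently, whereas the estimated correlation of that list in the real data was 0.152. The simulation therefore could not show how camera behaves with correlated genes. Named genes were chosen by a rule fixed beforehand: the 12 largest falls and 12 largest rises among genes changed against both controls with the miR-520f arrays apart from all control arrays, 10 genes named in advance, up to 4 members of each list called against both controls or, where none was, the 4 largest, and the 6 largest rises and 6 largest falls between the controls.

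Alternatives covered the replicate number as a block, the unmoderated fit, eBayes with trend and robust settings, fits of only the groups compared, the mean of all probe sets of a gene, all probe sets, removal of the dimmest genes, a further quantile normalization, median centring, array weights, a fold change of at least 1.5, and each array left out in turn. A test of genes by matches of the microRNA seed in the untranslated regions of their transcripts was planned and not run, because untranslated sequences were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.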

Results

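Gene expression was measured in PANC-1 cells, an epithelial line established from a human pancreatic carcinoma, 72 h after transfection with a synthetic microRNA mimic. A mimic is a short double-stranded RNA that enters the silencing complex of the cell and acts as the microRNA it copies. The 9 arrays fell into 3 groups of 3 biological replicates. Non-transfected cells received the lipid reagent alone, negative control cells received 20 nM of a mimic of control sequence, and miR-520f cells received 20 nM of a miR-520f mimic. The values were RMA log2 intensities of 22011 probe sets, and 14232 genes had a probe set of their own and were tested. Array medians lay between 4.22 and 4.34, and the number of arrays limits the precision of every value below. In a principal component analysis of the tested genes the first component held 54.8% of the variance and placed the 3 miR-520f arrays between 28.7 and 30.7, with the 6 control arrays between -20.0 and -13.2. The second component held 23.1% and separated the non-transfected arrays (14.9 to 18.0) from the negative control arrays (-24.0 to -10.9). Replicate 1 of the negative control lay farthest from its group, with a root mean square deviation of 0.169 from the group mean against 0.0698 to 0.131 for the other 8 arrays.

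**Figure D1:**
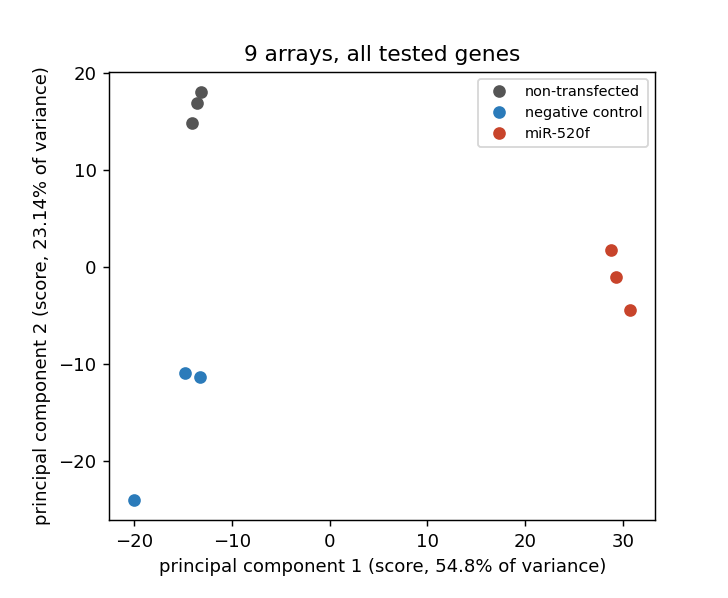
Scores of the 9 arrays on principal components 1 (54.8% of the variance) and 2 (23.1%) of all tested genes, 1 point per array, coloured by group. The miR-520f arrays lie at 28.7 to 30.7 on component 1 and all control arrays below -13.

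The comparison of miR-520f with both controls addressed which genes the microRNA changed, and the study took genes that were higher, or lower, than in both controls as targets. NOG, a secreted antagonist of bone morphogenetic proteins, showed the largest fall by the smaller of its fold changes against the controls, from 8.64 ± 0.13 in non-transfected and 8.50 ± 0.35 in negative control cells to 5.59 ± 0.12 with miR-520f (log2 values, SD, n = 3 each; probe set 3727928). Its log2 fold changes were -3.05 (SE 0.15, limma adjusted p = 2.84e-07) and -2.91 (SE 0.15, limma adjusted p = 3.01e-07). IL6ST, the signalling receptor chain shared by interleukin-6 cytokines, fell with log2 fold changes of -2.35 and -2.56 against non-transfected and negative control cells, in that order, as in the pairs of values that follow. On the side of the rises, DEPTOR, an inhibitor of mTOR, went from 5.74 ± 0.17 and 5.47 ± 0.19 to 8.10 ± 0.11 (SD, n = 3 each; log2 fold changes 2.36 and 2.63), and the interleukin-6 receptor IL6R rose by 2.38 and 1.92. EPCAM, an adhesion molecule of epithelial cells, rose from 7.80 ± 0.05 and 7.69 ± 0.13 to 9.37 ± 0.20 (SD, n = 3 each).

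Among 14232 genes, limma found 3927 that differed between miR-520f and non-transfected cells (2061 higher and 1866 lower with miR-520f) and 3996 that differed between miR-520f and negative control cells (2196 higher and 1800 lower). Against both controls, 1333 genes rose and 1226 fell, 2559 in all, and 62 genes passed in both with opposite signs. The balance of rises and falls depended on scaling, with 1256 higher and 1336 lower after a further quantile normalization and 1546 and 1013 with arrays centred on the median. In 2525 of the 2559, all 3 miR-520f arrays lay on one side of all 6 control arrays, which the selection of these genes favours. Over all genes this held for 25.4%, where chance gives 2.38%. At a fold change of at least 2 as well, 85 genes rose and 160 fell against both controls. The fold changes of the comparisons correlated across genes (r = 0.764, covariance 0.120), where simulated unchanged groups that share the miR-520f arrays gave r = 0.503 and a covariance of 0.00560. Those simulations gave on average 158 genes of equal sign at an unadjusted p under 0.05 in both comparisons, against 3375 observed, and 0 genes at the adjusted threshold. That 0 follows from simulating no effect. Independent lists of the observed sizes would share 318 higher and 236 lower genes. The shared arrays were not split between the comparisons, so part of the excess over independent lists may come from them.

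**Figure D2:**
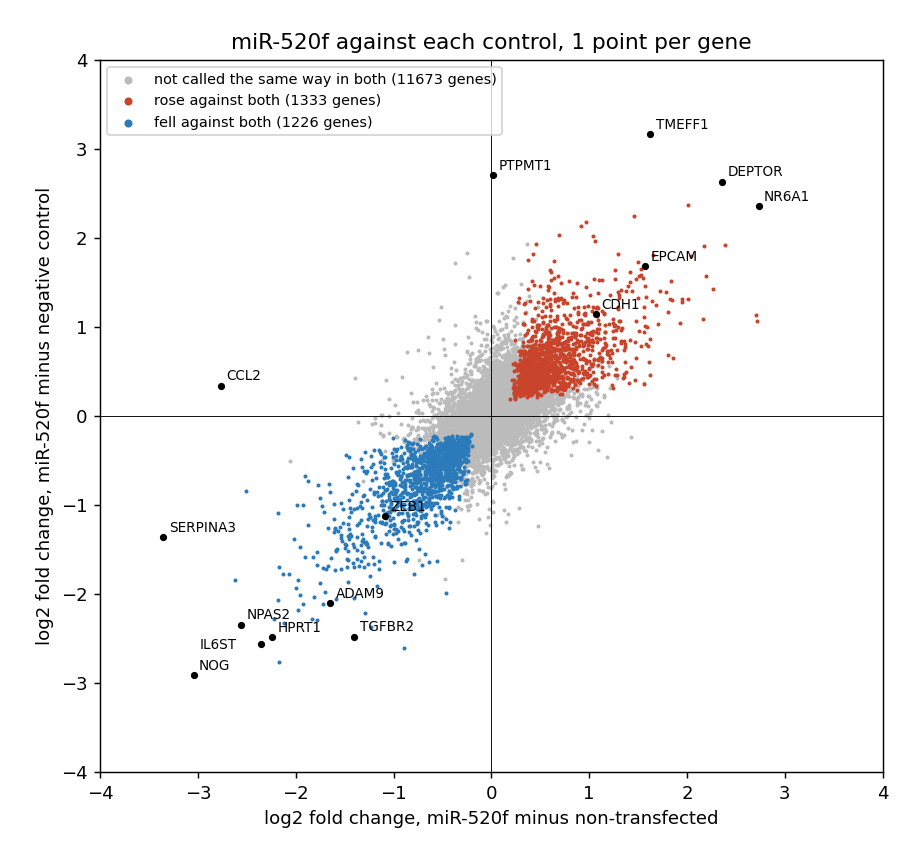
Log2 fold change of miR-520f minus non-transfected (x axis) and minus negative control (y axis), 1 point per gene over 14232 genes, red for the 1333 genes that rose and blue for the 1226 that fell against both controls, and black for genes with a label. NOG lies at -3.05 and -2.91, DEPTOR at 2.36 and 2.63, and PTPMT1 at 0.02 and 2.71.

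The 12 largest falls, ranked by the smaller of the log2 fold changes against the controls, also held NPAS2, a circadian transcription factor (-2.56 and -2.34), and HPRT1, an enzyme of purine salvage (-2.25 and -2.48). TMEM14A (-2.23 and -2.28), EPDR1 (-2.12 and -2.32), FAM43A (-1.95 and -2.01) and the ubiquitin ligase AREL1 (-1.93 and -2.11) were of similar size. IRAK2, a kinase downstream of interleukin-1 and Toll-like receptors, had log2 fold changes of -2.18 and -2.76, from a negative control level that was itself higher than in non-transfected cells by 0.58. The remaining falls were the vesicle SNARE VAMP3 (-2.18 and -2.06), the inositol phosphatase OCRL (-1.98 and -2.17) and the ESCRT-III subunit CHMP3 (-2.00 and -1.93).

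Among the 12 largest rises, DNMT3B, a DNA methyltransferase, rose by 1.65 and 1.81, TET1, which oxidizes methylcytosine, by 2.19 and 1.58, the nuclear receptor NR6A1 by 2.73 and 2.36 and the transcription factor SALL4 by 1.53 and 1.65. Also among these rises were the Mediator kinase CDK8 (2.17 and 1.91), the lysosomal protease CTSV (2.04 and 1.80) and the protease inhibitor SPINT1 (2.01 and 2.37). TMEFF1 rose by 1.62 and 3.17, and its level in negative control cells was lower than in non-transfected cells by a log2 fold change of -1.54. CHORDC1, a co-chaperone of HSP90, had log2 fold changes of 1.55 and 1.55 with a wide error (SE 0.47, limma adjusted p = 0.0307 and 0.0307), and each of its calls was lost under 7 of the alternative settings.

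ADAM9, a membrane metalloprotease, and TGFBR2, the type II receptor of TGF-beta, are the targets the study is known for, and both fell. ADAM9 (probe set 3095002) went from 8.40 ± 0.31 in non-transfected and 8.85 ± 0.05 in negative control cells to 6.75 ± 0.29 with miR-520f (SD, n = 3 each), with log2 fold changes of -1.65 and -2.10 (SE 0.16 each; limma adjusted p = 2.52e-05 and 4.39e-06). TGFBR2 (probe set 2615360) measured 8.08 ± 0.06, 9.16 ± 0.09 and 6.68 ± 0.11 in the same groups, so its fold change depended on the control: -1.40 against non-transfected cells and -2.48 against the negative control, in which it stood 1.08 above non-transfected cells (limma adjusted p = 2.66e-05). Both of these genes fell over all genes and adjusted over the list alone, which is not independent evidence, since the study took its targets, rises and falls alike, from these arrays.

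Genes of the epithelial and mesenchymal states were examined next. E-cadherin, CDH1, rose from 5.54 ± 0.09 and 5.46 ± 0.07 to 6.61 ± 0.05 (SD, n = 3 each; log2 fold changes 1.07 and 1.15), and ZEB1, a transcriptional repressor of CDH1, fell (log2 fold changes -1.08 and -1.12). N-cadherin, CDH2, fell (-0.26 and -0.30) at low levels, 4.14 to 4.28 on the control arrays and 3.89 to 3.98 on the miR-520f arrays. Vimentin, VIM, among the brightest probe sets, had log2 fold changes of -0.23 and -0.24 (limma adjusted p = 0.0366 and 0.0326). The VIM calls were lost under 9 and 6 alternative settings, a further quantile normalization and median centring of the arrays among them. Centring, or leaving out non-transfected replicate 2 or miR-520f replicate 2, ended the call of CDH2 against non-transfected cells. ZEB2, SNAI1, SNAI2 and TWIST1 were not called, with log2 fold changes of -0.03 and -0.13, 0.28 and 0.04, 0.00 and -0.06 and 0.09 and 0.07. The levels of ZEB2 and SNAI2 were near the lower end of the scale, at 2.97 ± 0.03 and 2.89 ± 0.03 with miR-520f (SD, n = 3 each).

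Of 38 measured epithelial markers, 10 rose and 2 fell against both controls. The median level over members and arrays was 3.92 for this list and 4.01 for the mesenchymal markers, so many members were dim. In the separate comparisons 12 rose, 2 fell and 24 were not called against non-transfected cells (12 and 2 adjusted over the list alone), and 12 rose, 2 fell and 24 were not called against the negative control (13 and 2 adjusted over the list alone). Besides CDH1 and EPCAM, SPINT1 and the tight junction gene CLDN4 (1.08 and 1.23) rose. The falls were in the keratin KRT19 (-0.75 and -0.68) and the mucin MUC1 (-1.35 and -1.01), names taken after their values were seen. Camera called the list higher against the negative control (adjusted p = 0.0147; adjusted p = 0.713 with an estimated correlation) and not against non-transfected cells (adjusted p = 0.0624). Against non-transfected cells the list passed after a further quantile normalization, without non-transfected replicate 3 and without miR-520f replicate 3. Of 36 mesenchymal markers, 3 rose and 7 fell against both controls. Separately, 3 rose, 10 fell and 23 were not called against non-transfected cells (3 and 10 adjusted over the list alone), and 6 rose, 8 fell and 22 were not called against the negative control (6 and 8 adjusted over the list alone). The adhesion receptor CD44 (-1.57 and -1.29), the receptor kinase AXL (-1.40 and -2.04) and the matrix protein TGFBI (-1.64 and -1.59) fell. The transcription factor TCF4 (0.93 and 1.04), the integrin ITGA5 (1.40 and 0.37) and the matrix protein SPARC (0.76 and 0.55), named after their values were seen, rose, and camera called the list in neither comparison (adjusted p = 0.271 and 0.513).

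**Figure D3:**
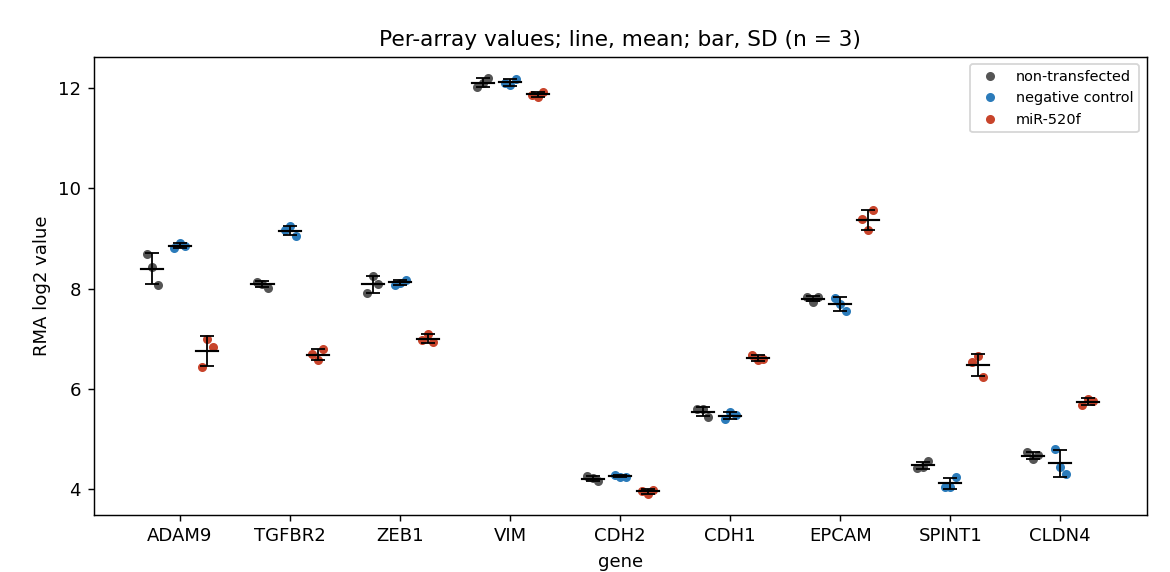
RMA log2 values of 9 genes on each array (points, spread sideways within a group) with the group mean (line) and SD (bar, n = 3), for non-transfected, negative control and miR-520f cells. ADAM9, TGFBR2 and ZEB1 are lower and CDH1, EPCAM, SPINT1 and CLDN4 higher with miR-520f, while VIM differs by -0.23 and -0.24.

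Among 33 measured components of the TGF-beta pathway, 12 rose, 9 fell and 12 were not called against non-transfected cells (12 and 10 adjusted over the list alone), and 9 rose, 7 fell and 17 were not called against the negative control (9 and 8 adjusted over the list alone). Besides TGFBR2, the latent TGF-beta binding protein LTBP2 fell (-2.13 and -1.77), while the co-receptor TGFBR3 (1.83 and 1.51) and the activin receptor ACVR2B (1.33 and 0.96) rose. Of 27 genes that TGF-beta controls, 3 rose, 9 fell and 15 were not called against non-transfected cells (3 and 9 adjusted over the list alone), and 4 rose, 7 fell and 16 were not called against the negative control (5 and 7 adjusted over the list alone). TGFBI, LTBP2, the feedback regulator PMEPA1 (-1.46 and -1.27) and the transglutaminase TGM2 (-1.09 and -0.83) fell against both controls. SKIL (0.57 and 0.50), KLF10 (0.70 and 0.43) and CCN2 (0.41 and 0.61), also named after their values were seen, rose. Camera called neither list (adjusted p = 0.587 and 0.513 for the components, 0.0624 and 0.513 for the target genes). The target genes against non-transfected cells passed with arrays centred on the median, without the dimmest genes and without some single arrays. In the list of ADAM proteases, matrix metalloproteases and their inhibitors, 24 genes were measured, of which 3 rose, 4 fell and 17 were not called against non-transfected cells (3 and 4 adjusted over the list alone), and 5 rose, 5 fell and 14 were not called against the negative control (5 and 5 adjusted over the list alone). The inhibitor TIMP1 fell (-1.25 and -1.10), ADAM15 fell (-0.46 and -0.63) and MMP16 rose (0.87 and 0.78). Of 26 matrix and integrin genes, 6 rose, 6 fell and 14 were not called against non-transfected cells (6 and 6 adjusted over the list alone), and 3 rose, 5 fell and 18 were not called against the negative control (3 and 5 adjusted over the list alone). COL5A2 (0.73 and 0.64) and the laminin chain LAMB1 (0.63 and 0.83) rose, and the integrins ITGA2 (-0.55 and -0.98) and ITGA3 (-0.79 and -0.48) fell.

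Among 10 published targets of microRNAs of related seed that were measured, 7 fell with miR-520f against both controls. RELA, the NF-kappaB subunit p65, fell (-1.67 and -1.68), as did CD44 (-1.57 and -1.29) and the GTPase RHOC (-0.95 and -1.09). The kinase WEE1, also on that list, rose (0.99 and 0.53; chosen after its values were seen). In each comparison 1 rose, 7 fell and 2 were not called against non-transfected cells (1 and 7 adjusted over the list alone), and 1 rose, 7 fell and 2 were not called against the negative control (1 and 7 adjusted over the list alone). Camera called the list lower against non-transfected cells (adjusted p = 0.00134; adjusted p = 0.160 with an estimated correlation) and against the negative control (adjusted p = 0.000939; adjusted p = 0.141 with an estimated correlation). TGFBR2 is on this list too and is not independent of these arrays.

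Of 37 measured genes of the G2 and M phases, 17 rose and 2 fell against both controls, among them the kinetochore gene NDC80 (1.01 and 0.94), the topoisomerase TOP2A (1.01 and 0.92) and the kinase AURKA (1.17 and 0.80), which rose. By comparison, 31 rose, 2 fell and 4 were not called against non-transfected cells (32 and 2 adjusted over the list alone), and 17 rose, 2 fell and 18 were not called against the negative control (21 and 4 adjusted over the list alone). Camera called the list higher against non-transfected cells (adjusted p = 8.48e-14; adjusted p = 0.160 with an estimated correlation) and against the negative control (adjusted p = 0.00190; adjusted p = 0.713 with an estimated correlation). Cyclin B1, CCNB1 (-0.59 and -0.77), and CENPF (-0.73 and -1.32) fell and were named after their values were seen. Of 32 S phase genes, 23 rose, 3 fell and 6 were not called against non-transfected cells (25 and 5 adjusted over the list alone), and 9 rose, 7 fell and 16 were not called against the negative control (10 and 7 adjusted over the list alone). Cyclin E1, CCNE1 (1.53 and 1.59), and the primase subunit PRIM1 (1.47 and 0.83) rose against both controls, while UHRF1, which maintains DNA methylation (-1.47 and -1.60), and CDCA7 (-0.81 and -0.81) fell. Camera called the S phase list against non-transfected cells (adjusted p = 1.53e-09; adjusted p = 0.386 with an estimated correlation) and not against the negative control (adjusted p = 0.533). Of 20 cell cycle inhibitors and G1 regulators, 6 rose, 3 fell and 11 were not called against non-transfected cells (7 and 3 adjusted over the list alone), and 5 rose, 3 fell and 12 were not called against the negative control (5 and 4 adjusted over the list alone). The kinase CDK6 rose (2.16 and 1.09), whereas cyclin D2, CCND2 (-0.89 and -2.60), and the inhibitor CDKN1A (-0.89 and -0.83) fell, with no call for the list (adjusted p = 0.166 and 0.745).

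In the interferon response and NF-kappaB lists, more members fell with miR-520f against non-transfected cells than against the negative control. That difference between the comparisons was not tested. Of 39 interferon response genes, 0 rose and 9 fell against both controls, including PARP14 (-1.49 and -1.44), DTX3L (-1.61 and -1.16), IFIT5 (-1.07 and -0.69) and UBE2L6 (-0.97 and -0.65). Taken singly, 0 rose, 19 fell and 20 were not called against non-transfected cells (0 and 20 adjusted over the list alone), and 4 rose, 9 fell and 26 were not called against the negative control (4 and 9 adjusted over the list alone). Camera called the list lower against non-transfected cells (adjusted p = 9.70e-08; adjusted p = 0.316 with an estimated correlation) and not against the negative control (adjusted p = 0.570). Of 23 NF-kappaB and inflammatory genes, 0 rose in either comparison and 3 fell in both: RELA, IER3 (-0.96 and -0.96) and LIF. LIF lay at 4.71 to 5.07 on the miR-520f arrays and at 5.91 to 6.62 on the control arrays. In the list as a whole, 0 rose, 9 fell and 14 were not called against non-transfected cells (0 and 11 adjusted over the list alone), and 0 rose, 6 fell and 17 were not called against the negative control (0 and 6 adjusted over the list alone). Camera called it lower against non-transfected cells (adjusted p = 9.46e-05; adjusted p = 0.215 with an estimated correlation) and the negative control (adjusted p = 0.0294; adjusted p = 0.713 with an estimated correlation). The second call was lost without negative control replicate 2 and without miR-520f replicate 3.

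Of 23 genes of the integrated stress response, 11 rose, 3 fell and 9 were not called against non-transfected cells (12 and 3 adjusted over the list alone), and 6 rose, 5 fell and 12 were not called against the negative control (6 and 5 adjusted over the list alone). STC2 (1.42 and 0.86) and the transcription factor DDIT3 (1.09 and 0.64) rose, and VLDLR (-0.46 and -0.65) and DDIT4 (-0.42 and -0.61) fell. Camera called the list higher against non-transfected cells (adjusted p = 0.00861; adjusted p = 0.552 with an estimated correlation), a call lost after a further quantile normalization. Of 24 p53 target genes, 6 rose, 4 fell and 14 were not called against non-transfected cells (6 and 5 adjusted over the list alone), and 6 rose, 10 fell and 8 were not called against the negative control (7 and 11 adjusted over the list alone). SESN1 (0.76 and 0.78), TP53INP1 (0.71 and 1.32) and MDM2 (0.97 and 0.60) rose. The inhibitor CDKN1A fell (-0.89 and -0.83), as did GADD45A (-0.39 and -0.67) and DDB2 (-0.56 and -0.25), both named after their values were seen. Of 20 chaperones of the endoplasmic reticulum, 3 rose, 1 fell and 16 were not called against non-transfected cells (3 and 1 adjusted over the list alone), and 6 rose, 2 fell and 12 were not called against the negative control (8 and 4 adjusted over the list alone). DNAJC3 rose against both controls (0.58 and 1.46). Of 16 genes of cholesterol synthesis, 1 rose, 5 fell and 10 were not called against non-transfected cells (1 and 6 adjusted over the list alone), and 2 rose, 7 fell and 7 were not called against the negative control (3 and 7 adjusted over the list alone). STARD4 (-0.62 and -0.66), SC5D (-0.50 and -0.69) and DHCR7 (-0.60 and -0.28) fell. Of 26 genes of hypoxia and glycolysis, 3 rose, 10 fell and 13 were not called against non-transfected cells (3 and 11 adjusted over the list alone), and 4 rose, 6 fell and 16 were not called against the negative control (4 and 8 adjusted over the list alone). Adrenomedullin, ADM, rose (1.30 and 1.82), and hexokinase HK2 (-0.99 and -0.77) and BNIP3L (-0.63 and -0.86) fell. Of 19 immediate early and heat shock genes, 7 rose, 4 fell and 8 were not called against non-transfected cells (7 and 4 adjusted over the list alone), and 7 rose, 3 fell and 9 were not called against the negative control (9 and 3 adjusted over the list alone). DUSP1 (-0.89 and -0.99) and JUN (-0.61 and -0.90) fell and EGR1 rose (0.83 and 0.72). Apart from the integrated stress response against non-transfected cells, camera called none of these 6 lists in either comparison.

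Of 23 genes of MAPK output, 7 rose, 7 fell and 9 were not called against non-transfected cells (7 and 7 adjusted over the list alone), and 8 rose, 6 fell and 9 were not called against the negative control (8 and 8 adjusted over the list alone). The transcription factor ETV1 (1.81 and 1.17) and the feedback inhibitor SPRY2 (0.84 and 0.94) rose, and FOSL1 fell (-1.15 and -1.63). Of 21 YAP target genes, 7 rose, 6 fell and 8 were not called against non-transfected cells (7 and 6 adjusted over the list alone), and 8 rose, 7 fell and 6 were not called against the negative control (8 and 8 adjusted over the list alone). The ectonucleotidase NT5E (-1.70 and -1.98) and DOCK5 (-1.46 and -1.51) fell and the kinase NUAK2 rose (1.95 and 1.32). Of 22 apoptosis regulators, 5 rose, 2 fell and 15 were not called against non-transfected cells (5 and 2 adjusted over the list alone), and 5 rose, 4 fell and 13 were not called against the negative control (5 and 5 adjusted over the list alone). The effector BAK1 rose (1.38 and 1.41), and CASP8 (-0.77 and -0.98) and BCL2L1 (-0.94 and -0.61) fell. Of 19 genes of the microRNA machinery, 5 rose, 3 fell and 11 were not called against non-transfected cells (5 and 3 adjusted over the list alone), and 7 rose, 7 fell and 5 were not called against the negative control (7 and 7 adjusted over the list alone). The decapping enzyme DCP2 (2.70 and 1.13) and the Argonaute gene AGO2 (0.93 and 0.53) rose, and the deadenylase subunits CNOT6 (-1.17 and -1.90) and PAN3 (-0.84 and -1.03) fell. Of 19 genes of drug resistance and stemness, 5 rose, 3 fell and 11 were not called against non-transfected cells (5 and 3 adjusted over the list alone), and 2 rose, 4 fell and 13 were not called against the negative control (2 and 4 adjusted over the list alone). The transporter ABCC3 (-2.62 and -1.85) and CD24 (-1.13 and -0.57) fell, and the cytidine deaminase CDA rose (0.57 and 0.59). Of 16 ribosomal protein genes, 1 rose, 0 fell and 15 were not called against non-transfected cells (1 and 0 adjusted over the list alone), and 3 rose, 1 fell and 12 were not called against the negative control (3 and 1 adjusted over the list alone). RPL6 rose against both controls (0.69 and 0.99). Camera called none of these 6 lists in either comparison with miR-520f.

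Of 10 replication-dependent histone genes, 0 rose, 2 fell and 8 were not called against non-transfected cells (0 and 0 adjusted over the list alone), and 0 rose, 7 fell and 3 were not called against the negative control (0 and 8 adjusted over the list alone). H2BC21 (-0.58 and -0.72) and H2BC5 (-0.47 and -0.48) fell against both controls. Their calls were lost under 3 to 11 alternative settings each. Camera called the histone list lower against the negative control (adjusted p = 0.00299; adjusted p = 0.713 with an estimated correlation) and not against non-transfected cells (adjusted p = 0.676). Markers of other cell types were mostly near the lower end of the scale, with medians over members and arrays of 3.14 for fibroblast, 3.17 for endothelial, 3.39 for immune, 3.44 for acinar and 3.33 for endocrine markers. Of 9 fibroblast markers, 0 rose, 2 fell and 7 were not called against non-transfected cells (0 and 2 adjusted over the list alone), and 0 rose, 1 fell and 8 were not called against the negative control (0 and 1 adjusted over the list alone). COL6A3 fell against both controls (-0.50 and -0.68). Of 11 immune markers, 1 rose, 1 fell and 9 were not called against non-transfected cells (1 and 1 adjusted over the list alone), and 1 rose, 1 fell and 9 were not called against the negative control (1 and 1 adjusted over the list alone). CD68, a lysosomal protein of macrophages, fell (-1.31 and -0.90) from a level of 8.65 ± 0.21 in non-transfected cells (SD, n = 3), and TYROBP rose (0.52 and 0.44). Of 11 endothelial markers, 0 rose, 0 fell and 11 were not called against non-transfected cells (0 and 0 adjusted over the list alone), and 0 rose, 0 fell and 11 were not called against the negative control (0 and 0 adjusted over the list alone). The endothelial marker ESAM had log2 fold changes of -0.07 and -0.09. Of 4 measured acinar markers, 0 rose, 0 fell and 4 were not called against non-transfected cells (0 and 0 adjusted over the list alone), and 0 rose, 0 fell and 4 were not called against the negative control (0 and 0 adjusted over the list alone). Of 7 endocrine markers, 0 rose, 1 fell and 6 were not called against non-transfected cells (0 and 1 adjusted over the list alone), and 0 rose, 0 fell and 7 were not called against the negative control (0 and 0 adjusted over the list alone). CHGB was the endocrine gene called against non-transfected cells (-0.67). Alternative settings also ended the calls of ADAM15, ITGA2, DDIT4, STARD4, DNAJC3, TYROBP and RPL6 against non-transfected cells, and those of UBE2L6, CD24, BCL2L1, DHCR7, STARD4 and TYROBP against the negative control. In a few uncalled lists the median, the mean and the direction of camera differed in sign. Against non-transfected cells these were matrix and integrins (median -0.02, mean 0.05, camera up), MAPK output (-0.02, 0.09, up) and YAP targets (0.03, -0.11, down). Against the negative control they were G1 regulators (-0.01, -0.04, up), apoptosis regulators (-0.03, 0.01, up) and microRNA machinery (0.02, -0.09, down).

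The controls themselves were compared to measure the effect of transfecting a mimic of control sequence. CCL2, a chemokine that attracts monocytes, showed the largest fall, from 9.61 ± 0.11 in non-transfected to 6.50 ± 0.66 in negative control cells (SD, n = 3 each; log2 fold change -3.11, SE 0.25, limma adjusted p = 3.50e-05). In miR-520f cells it stood at 6.84 ± 0.19. The mitochondrial phosphatase PTPMT1 had a log2 fold change of -2.69 and the receptor kinase MET of -2.09, and with miR-520f PTPMT1 stood at 8.79 ± 0.13 and MET at 7.90 ± 0.18, against 8.78 ± 0.09 and 8.27 ± 0.05 in non-transfected cells (SD, n = 3 each). SERPINA3, a protease inhibitor of the acute phase, fell with both mimics against non-transfected cells (-1.99 with the control and -3.35 with miR-520f). Among the rises were cyclin D2, CCND2 (1.71), the ubiquitin ligase subunit SKP2 (1.66), STK40 (1.71), SCML2 (1.64), GXYLT1 (1.63) and DCP2 (1.57).

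Limma found 2174 genes that differed between negative control and non-transfected cells, 996 higher and 1178 lower with the control mimic, of which 121 also had a fold change of at least 2. With arrays centred on the median 999 were higher and 924 lower, and without non-transfected replicate 1 942 were higher and 865 lower, so the balance of directions depended on these choices. A fit without moderation of the spread called 1287 genes, and 1394 were called without non-transfected replicate 2. Of the 2559 genes that miR-520f changed against both controls, 599 (23.4%) also differed between the controls. Against non-transfected cells, 997 genes moved the same way with both mimics (536 higher and 461 lower) and 295 moved in opposite directions. Independent lists of these sizes would share 144.2 higher and 154.5 lower genes. Simulated unchanged groups that share the non-transfected arrays gave 0, which follows from simulating no effect of either mimic. At an unadjusted p under 0.05 in both, 1656 genes moved the same way, where the simulations gave 153.2. Across genes the covariance of the fold changes was 0.0334, where those simulations gave 0.00551, with r = 0.313 against 0.497. The share of genes with equal sign was 57.6%, below the 66.7% of those simulations. The shared non-transfected arrays were not split, so part of the excess over independent lists may come from them.

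Of 39 interferon response genes, 0 rose, 18 fell and 21 were not called (0 rose and 21 fell adjusted over the list alone) with the control mimic against non-transfected cells. IFIT1 (-2.07) and IFIT2 (-1.82), which bind viral RNA, and DTX3L (-0.45; a call lost under 4 alternative settings) fell, and camera called the list lower (adjusted p = 1.52e-10; adjusted p = 0.201 with an estimated correlation). With miR-520f, IFIT1 stood at 7.19 ± 0.08 against 7.43 ± 0.23 in non-transfected and 5.36 ± 0.22 in negative control cells (SD, n = 3 each). Of 32 S phase genes, 24 rose, 0 fell and 8 were not called (24 rose and 0 fell adjusted over the list alone). PRIM1 rose (0.64; a call lost without moderation of the spread), and camera called the list higher (adjusted p = 2.19e-15; adjusted p = 0.201 with an estimated correlation). Of 37 genes of the G2 and M phases, 17 rose, 0 fell and 20 were not called (21 rose and 0 fell adjusted over the list alone). AURKA rose (0.37; a call lost under 4 alternative settings), and the list was called higher (adjusted p = 7.52e-10; adjusted p = 0.201 with an estimated correlation). Of 20 cell cycle inhibitors and G1 regulators, 7 rose, 0 fell and 13 were not called (7 rose and 0 fell adjusted over the list alone), with CDK6 at 1.07 besides CCND2, and camera called the list higher (adjusted p = 0.00897; adjusted p = 0.201 with an estimated correlation). That call was lost without negative control replicate 2.

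Of 19 genes of the microRNA machinery, 8 rose, 2 fell and 9 were not called (8 rose and 2 fell adjusted over the list alone). DCP2 and CNOT6 (0.74) rose, as did AGO2 (0.40; a call lost under 8 alternative settings), and the list was called higher (adjusted p = 0.00277; adjusted p = 0.449 with an estimated correlation). Of 10 histone genes, 5 rose, 0 fell and 5 were not called (7 rose and 0 fell adjusted over the list alone), with the list higher (adjusted p = 0.000429; adjusted p = 0.449 with an estimated correlation). The linker histone H1-2 (0.96) and H3C2 (0.76) were among those that rose, named after their values were seen. Of 23 genes of the integrated stress response, 6 rose, 1 fell and 16 were not called (8 rose and 1 fell adjusted over the list alone). STC2 (0.56) and DDIT3 (0.45) rose, although alternative settings ended the DDIT3 call in 11 cases and the STC2 call in 2. Camera called this list higher (adjusted p = 0.0118; adjusted p = 0.454 with an estimated correlation), and the call was lost without negative control replicate 2 and without non-transfected replicate 3. Of 36 mesenchymal markers 3 rose and 4 fell, and of 38 epithelial markers 1 rose and 4 fell, with no call for either list and, for the mesenchymal markers, a median of 0.03 and a mean of -0.03 (adjusted p = 0.968 and 0.188). Of 23 NF-kappaB and inflammatory genes 0 rose and 5 fell, CCL2 among them (adjusted p = 0.157 by camera). Camera called 7 of the 29 lists it tested in this comparison, 6 for miR-520f against non-transfected cells and 5 against the negative control. With an estimated correlation it called 0 in each, where 4, 4 and 1 lists had an unadjusted p under 0.05, and fry called 12, 17 and 12.

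**Figure D4:**
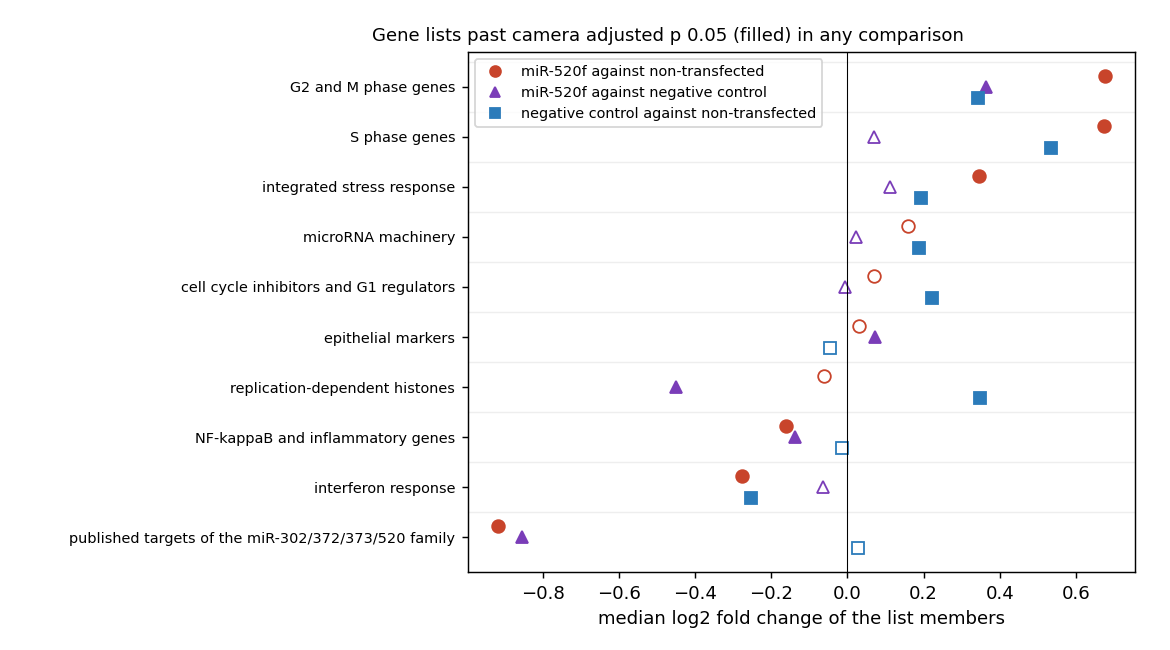
Median log2 fold change over the members of each of the 10 gene lists that camera called in any of the 3 comparisons (circles, miR-520f minus non-transfected; triangles, miR-520f minus negative control; squares, negative control minus non-transfected). Filled symbols passed an adjusted p of 0.05 with the preset correlation, and the interferon response list lies at -0.28 and -0.25 in both comparisons with non-transfected cells.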

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

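Probe sets without a single gene of their own stood outside the comparisons of genes, and a number of them moved with miR-520f, which is why they are given here. In a fit of all 22011 probe sets, 209 of the 5171 probe sets not named here changed the same way against both controls (85 higher and 124 lower, 4.04%). Among the 2408 probe sets with several genes, 293 did (154 higher and 139 lower, 12.2%). The single-gene probe sets gave 2256 of 14432 (15.6%) in that fit. The median level was 3.85 for probe sets not named here, 4.21 for those with several genes and 4.50 for those with a single gene. No explanation was tested for these shares.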

How the results depend on the processing

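All alternatives were planned before the data were examined, except median centring for the gene lists, which was added after seeing the data. The count of genes changed against both controls (2559) lay between 1940 without moderation of the spread and 2770 without negative control replicate 1, apart from array weights and the fold threshold. Under the fits listed in processing, 0 of the genes shared with the main calls changed sign. Genes called in both of such fits, which reuse the same arrays, can hardly differ in sign, so that 0 is no independent evidence. With array weights, whose estimate stopped before it converged, 8575 genes differed for miR-520f against non-transfected cells, 6447 against the negative control, 4842 the same way against both, and 4997 between the controls. The lowest weight was 0.189, for negative control replicate 1. A fold change of at least 1.5 on top of the adjusted p left 1589, 1705, 929 and 678 genes in that order, by construction fewer. The fit without moderation gave 1287 genes between the controls in place of 2174. Leaving out each array in turn gave 1394 (without non-transfected replicate 2) to 2181, and the cause of this range was not tested. Median centring raised the share of higher genes among those changed against both controls from 52.1% to 60.4%, whereas it was 48.5% after a further quantile normalization, 49.1% without moderation and also without non-transfected replicate 3, 50.0% without miR-520f replicate 3 (1051 and 1052) and 45.2% with the fold threshold. Centring shifted the median log2 fold change over all genes against non-transfected cells from -0.03 to 0.04.

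Camera with an estimated correlation called 0 gene lists in each comparison in place of 6, 5 and 7. The estimates exceeded the preset 0.01 for called lists such as histones (0.460), S phase (0.321) and G2 and M phase (0.152). They lay close to it for G1 regulators (0.0121) and below it for the published microRNA targets (-0.0443). Yet the unadjusted camera p rose from 0.00186 to 0.0222 for G1 regulators between the controls. For the published targets against non-transfected cells it rose from 0.000232 to 0.00851. A larger correlation thus cannot account for each lost call, so these losses do not by themselves measure correlation between genes. What else this setting changes was not tested. Fry, which asks only whether members move one way, called 17, 12 and 12. Among these were epithelial markers, called higher against both controls (fry adjusted p = 0.00119 and 0.000884). Mesenchymal markers (fry adjusted p = 0.00635 and 0.00364) and TGF-beta target genes (fry adjusted p = 0.000453 and 0.00364) were called lower against both. Over all alternatives the lists kept direction and side of the threshold in 1235 values, lost a call in 25 and gained one in 36. For named genes the numbers were 7332, 190 and 83, and 0 called values turned direction. The alternatives reuse the same arrays, so the lack of turned calls is no independent evidence either. Samples of equal replicate number did not deviate together in each pair (correlations of -0.0262 to 0.205), and not every array correlated best with its own number. All pairs of numbers 2 and 3 were positive (0.0794 to 0.205), while pairs of different number ran from -0.437 to 0.330. A shared replicate effect therefore stays open. The labels do not say what a number shares, so it was not taken as a pairing. With the replicate number as a block, the counts were 4060, 4159, 2693 and 2297. Not run were the planned tests of seed matches. Signal over background was not used, so calls near the lower end of the scale rest on the deposited values alone.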

Other observations

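The tests on interferon genes as an explanation and the lists of reference genes and of targets of other microRNAs were chosen after the main results were seen, although the outcome of each test but the interferon test was not known when it was set. Targets of let-7, a microRNA that restrains growth and fetal genes, were examined against non-transfected cells. Of 24 let-7 targets outside the genes named by the rule fixed beforehand, 13 rose and 2 fell with miR-520f against non-transfected cells, and 10 rose and 0 fell with the control mimic, with medians of 0.43 and 0.23. The oncofetal RNA-binding protein LIN28B rose by 1.13 with miR-520f and 1.29 with the control mimic, IGF2BP2 by 0.91 and 0.76, and the transcription factor ARID3B by 1.19 and 0.72. HMGA2, an architectural chromatin protein, rose with miR-520f (1.30) and had a log2 fold change of -0.05 with the control mimic. Of 22 targets of miR-29, 8 rose and 0 fell with miR-520f and 5 rose and 2 fell with the control mimic (medians 0.17 and 0.06). Of 11 targets of miR-21, 4 rose and 2 fell with miR-520f and 3 rose and 3 fell with the control mimic (medians 0.01 and 0.02). Of 19 targets of liver, muscle and neuron microRNAs, 4 rose and 3 fell with miR-520f, and 2 rose and 4 fell with the control mimic (medians 0.02 and -0.05). These genes were named after their values were seen.

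Of 32 S phase genes, 23 rose with miR-520f and 24 with the control mimic against non-transfected cells, and several microRNA targets rose with both. A hypothesis is that the mimics compete with the microRNAs of the cell for the silencing complex, which may free the targets of abundant microRNAs. No microRNA was measured here, so which microRNAs are abundant in these cells was assumed. Targets of let-7, miR-29 and miR-21 outside the genes named by the rule fixed beforehand (57 genes) exceeded the 19 targets of other tissues' microRNAs by a mean log2 difference of 0.27 with the control mimic (one-sided permutation test over genes, p = 0.00523) and 0.40 with miR-520f (one-sided permutation test, p = 0.00093). Without any member of the lists fixed beforehand, the difference was 0.27 for the control mimic over 40 and 18 genes (one-sided permutation test, p = 0.00676) and 0.43 for miR-520f (one-sided permutation test, p = 0.00177). For miR-520f against the negative control, the difference over the 57 and 19 genes was 0.13 (one-sided permutation test, p = 0.182). Genes are not independent replicates, and the families were uneven (the miR-21 medians lay near those of the other tissues' targets). The tests against non-transfected cells share those arrays, and faster growth or the mimics' own targets stay open.

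The negative control mimic differed from the lipid reagent alone in 2174 genes. A deviant array is argued against by the 2094 genes called without negative control replicate 1. After a further quantile normalization 2319 genes were called, and 1923 with arrays centred on the median. RMA had already brought the arrays to a common distribution. A further normalization therefore changes little and cannot decide on a difference of scaling. A response to foreign RNA still under way at 72 h would raise interferon genes, whose median log2 change was -0.25, with 0 of 39 higher. These values were known when the test was set, and levels at 72 h cannot show an earlier response. The sequence of the control mimic, the transfected RNA itself and an unrecorded difference in handling between the groups stay open, since every array of a group shares them.

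HPRT1, a gene often used to normalize expression, fell with miR-520f (log2 fold changes -2.25 and -2.48). Scaling of the miR-520f arrays is argued against by 13 other reference genes, whose median log2 change against the negative control was 0.0005 with an interquartile range of 0.302. Of these, 0 fell and 1 rose against both controls, the TATA-binding protein gene TBP (0.64 and 1.08). A direct effect of miR-520f on HPRT1 and an indirect effect were not separated.

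Of the 840 splits of the 9 arrays into 3 groups of 3, 100 were drawn, the real one included. Only the real one gave as many as 2559 genes changed against both controls, and the highest other drawn gave 296. Mixed splits put arrays of different treatments in a group, which widens the spread within groups and lowers the count. Such draws therefore cannot exclude chance for this count. Each pair of groups allows 10 splits, too few for a share under 0.05. The real splits gave 3927, 3996 and 2174 genes for miR-520f against non-transfected cells, miR-520f against the negative control and the control mimic against non-transfected cells, and the highest other split gave 0 in each, so 1 of 10 splits reached the real count. For gene lists, 4 of 10 splits gave at least the 6 lists called for miR-520f against non-transfected cells (highest other 11), 1 of 10 gave the 5 called against the negative control (highest other 3), and 2 of 10 gave the 7 called between the controls (highest other 7). Camera thus called as many lists in some mixed groupings as in the real ones against non-transfected cells.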
